A study of Homo sapiens with 12 samples.

How the data were processed

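SOX2 ChIP-seq libraries of 2102EP and SOX17 ChIP-seq libraries of TCam-2, with 2% input libraries of each line, made up 4 groups of 3 libraries, taken from the sample titles. Per the labels' protocols, chromatin was fixed with a protein crosslinker and formaldehyde and digested enzymatically, and 200 µg of chromatin lysate and 5 µg of antibody went into each immunoprecipitation. Per the series' design text, single-end reads of 75 bp were sequenced at a planned 25 M reads per sample, mapped to hg38 with CLC Genomics Workbench 12 and analysed with HOMER. HOMER is also named in the submitters' processing notes. The HOMER version, the peak calling settings, the use of input in calling and the treatment of reads with several map positions are not given in the sources used here.

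The authors deposited 1 annotated peak list per factor, as merged peaks with no column for a single library. Each peak has a score, which the authors deposited without stating its scale. Multiplied by 3, the score was whole within rounding for 100% of SOX17 and 8.68% of SOX2 peaks, so the lists may not share a scale and scores were compared only within a list. Positions and distances to the TSS are in bp, and the authors gave them on hg38 with the nearest gene, annotation class and repeat, per the file headers. In each list 2 lines had been emptied before this work. Merged lists give no view of the replicates, and weak sites that were not called in them cannot be seen. All deposited peak names end in 3, whose meaning is not given in the sources used here. If it marks peaks called in all 3 replicates, a site absent from a list, such as that of POU5F1 for SOX17, can still have been called in a replicate, and the shared share of 25.3% applies to such peaks alone.

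A test of ChIP against input per peak was fixed in the design and was not run, because the lists hold no values per library. Before coordinates were used, the deposited distances were compared with TSSs of GENCODE 44 on hg38: of the 15779 SOX2 and 15599 SOX17 peaks whose gene was found there, 97.0% lay within 1000 bp of the distance to a TSS of the same gene in each list. The other peaks were not compared in this way, and no peak passed a chromosome end.

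Shared peaks had at least 1 bp in common. The random placement moved each SOX17 peak to its own signed distance from the TSS of a random gene, 1000 times. Target genes were the nearest genes of the deposited annotation, matched by gene number to 29978 RefSeq genes, of which the SOX2 list named 9319 and the SOX17 list 9742; 41 and 38 other genes had no match, and 29 and 27 peaks had no gene. Gene lists were tested against 10000 random lists matched on 10 groups of locus size, the distance between neighbouring TSSs. Locations and repeats were compared with two-sided Fisher's exact tests, and score medians with permutation tests of 100000 resamples. Adjusted p-values follow Benjamini and Hochberg within each family, with a threshold of 0.05. Very small p-values of Fisher's test were summed on a log scale. Intervals of shares are 95% Wilson intervals and those of odds ratios are 95% Woolf intervals. Tests and intervals between the lists treat peaks as independent. In fact 4426 regions are in both lists and copies of a repeat are alike in sequence, so these p-values and intervals are approximate. The percentile of a peak is its rank by score within its own list.

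Motifs were searched on both strands within 100 bp of the peak centre, and in windows of equal width 2000 bp to either side. The SOX site was CWTTGT, the OCT site ATGCWAAT and the AP-2 site GCCNNNGGC. Composite sites were a SOX site with no mismatch, 0 to 10 bases, and an OCT site with at most 1 mismatch, with 1 base for the canonical and 0 for the compressed spacing and the other 9 spacings as controls.

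The comparisons, tests, gene lists, first alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each list, the 10 highest scores with different nearest genes. It added the 10 shared peaks with the highest mean percentile, up to 4 members of each gene list by best percentile, 18 genes named in advance, and the 5 highest peaks per list and composite spacing. Outside this rule MYCN was named after its values were seen, as 1 of the 5 pluripotency genes near SOX2 peaks alone. Alternatives were other overlap and distance limits, some of them looser, a stricter score limit, other windows and mismatches, peaks outside promoters, uniform placement and Fisher's exact test for gene lists. Later additions, chosen after seeing the data, were peaks outside repeats and a mismatch in the SOX site.

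The steps were tested on simulated data. For the overlap of 17507 peaks, placement at random gave 28 shared peaks where 31.4 came by chance and 539 with 500 planted. The random peaks were placed by the same rule as the null of the test. This checks the counting and does not show that the null suits real peaks. For the gene lists, random peaks gave 0 calls in 280 tests by the matched test and 12 by Fisher's exact test. The pluripotency list, with 22 members planted near a peak, was called in 20 of 20 rounds. So large a number does not show how often lists near the threshold would be called. For the composite sites, 1100 of 1100 sites planted without a mismatch were found at their spacing among 4000 windows. At any 1 spacing, at most 5 windows were called that had no site planted at that spacing. Such calls were not totalled over the spacings. Sites with a mismatch were not planted. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, bedtools 2.31.1 and matplotlib 3.10.9.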

Results

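Binding of SOX2 and of SOX17 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in a pair of human germ cell tumour lines. SOX2 was precipitated from 2102EP, an embryonal carcinoma-like line, and SOX17 from TCam-2, a seminoma-like line. Each antibody was used on 3 biological replicates, and each line also gave 3 libraries of 2% input, so that 12 libraries fell into 4 groups. The values analysed were the authors' merged and annotated peaks, 1 list per factor. The lists hold no values per library and no read totals, so sequencing depth is unknown, no value below carries a replicate error, and intervals and p-values cover counting over peaks or genes but not the spread between cultures. Antibody and cell line changed together, and a difference between the lists is therefore a difference between the 2 experiments.

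The SOX2 list held 17795 peaks with a median width of 126 bp, and the SOX17 list 17507 peaks with a median width of 122 bp. The authors' peak score ran from 6.96 to 943 with a median of 24.1 for SOX2, and from 7.0 to 668 with a median of 26.7 for SOX17. Scores were used within a list, mostly as percentiles. The SOX2 peak of highest score lay in an intron of SOX5, a SOX family gene (hg38 chromosome 12, 23757656 to 23757788), and was followed by peaks nearest to the protocadherin gene PCDH1, PARP11, RESF1, RCC2, NLGN1-AS1, ETV6, DNAJB6, MIR620 and ITPRID1. In the SOX17 list the peak of highest score was assigned to the pseudogene BMS1P20, followed by the same SOX5 and PCDH1 regions and by peaks nearest to ZAP70, TEAD4, CPNE8, LINC02450, RNF130, COL17A1 and COL23A1. SOX5, PARP11, RESF1, ETV6 and TEAD4 lie on the short arm of chromosome 12, where scores of both lists ran higher than elsewhere: the median on that arm was 47.4 against 23.8 for SOX2 and 40.7 against 26.3 for SOX17. SOX17 scores were also high on chromosome 20, with a median of 36.3.

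The first comparison asked how far SOX2 and SOX17 occupied the same sites. They shared 4426 regions, which were 25.3% of the SOX17 peaks (95% Wilson interval 24.6 to 25.9%) and 24.9% of the SOX2 peaks (24.2 to 25.5%). The shared regions that stood highest in both lists were nearest to SOX5, PCDH1, ZHX2, COL17A1, MARCKS, PRDM14, MIRLET7I, ITPRID1, DPPA5 and ACVR1. PRDM14 encodes a regulator of pluripotency and germ cell specification, DPPA5 is expressed in pluripotent cells and ACVR1 encodes a BMP receptor. The PRDM14 region (chromosome 8, 69977420 to 69977553 in the SOX17 list) is intergenic, 93841 bp downstream of the transcription start site (TSS), and stood at percentiles 99.8 of the SOX2 and 99.9 of the SOX17 scores. The promoters of the Nodal co-receptor gene TDGF1 and of SOX15 were also shared, with SOX17 peaks at 3 and -172 bp from the TSS.

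Random placement of the SOX17 peaks at their own distances from the TSSs of random genes gave 31.8 shared peaks on average (SD 5.71 over 1000 placements, highest 54). The observed overlap was 139-fold higher and above every placement (two-sided empirical p of 0.002, the smallest that 1000 placements can give). That fold was 293 when each peak had to share 50% of its length, 249 for the higher-scoring 8907 SOX2 and 8832 SOX17 peaks, and 19.8 when peak centres within 1000 bp counted as shared. The placements kept the distance to a TSS but were not limited to open chromatin, mappable sequence or repeats. The fold and its p therefore do not show an overlap particular to these factors.

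Shared peaks had higher scores than unshared peaks in both lists. The median was 33.1 for 4426 shared and 22.1 for 13369 unshared SOX2 peaks, and 33.3 against 25.0 for SOX17, with 13081 unshared peaks (two-sided permutation tests with 100000 resamples, p = 1e-05 in each, the smallest they can give). Of the SOX2 peaks in the lowest score decile 12.5% were shared, against 48.9% in the highest. For SOX17 these shares were 16.1% and 38.1%, with a dip from 18.3% in decile 2 to 17.2% in decile 3. Across the shared regions the 2 scores had a Spearman correlation of 0.252, computed across regions, which are not independent replicates.

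At the level of nearest genes, 6203 genes had a peak in both lists, 3116 in the SOX2 list alone and 3539 in the SOX17 list alone, among 29978 background genes. Independent lists of these sizes would have 3028 genes in common (odds ratio 9.63, 95% interval 9.1 to 10.2; two-sided Fisher's exact test, p = 3.4e-1524). Long loci collect peaks of any factor, and this test does not allow for locus length. Of the 6203 genes, 3575 (57.6%) had a peak that overlapped between the lists, so that the remaining genes carried SOX2 and SOX17 peaks at different positions.

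NANOG, a core pluripotency gene on the short arm of chromosome 12, was of the latter kind: its SOX17 peak lay at -3712 bp from the TSS (chromosome 12, 7785634 to 7785735, percentile 99.9) and its SOX2 peak at -1656 bp (7787681 to 7787799, percentile 94.5). POU5F1, which encodes OCT4, had a SOX2 peak at -1361 bp from its TSS (chromosome 6, 31172002 to 31172106, percentile 88.6), and no peak of the SOX17 list was assigned to it. The genes LIN28B, whose product represses let-7 maturation, GDF3, a TGF-beta family ligand gene, and LEFTY2, a Nodal antagonist gene, also had 1 SOX2 peak each, at percentiles 96.4, 98.9 and 97.1, and none in the SOX17 list. GDF3, like NANOG, lies on the arm where scores ran higher. DPPA4 had 2 peaks in each list and both were shared, at the promoter (percentiles 90.9 for SOX2 and 58.8 for SOX17) and further upstream, with the SOX2 peak at -18288 bp (percentiles 99.03 for SOX2 and 80.0 for SOX17). DPPA2 had a SOX2 promoter peak at percentile 58.7 and a SOX17 peak 40563 bp downstream of its TSS at percentile 49.1.

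PRDM1, which encodes the germ cell specification factor BLIMP1, had 6 SOX2 and 8 SOX17 peaks, of which 3 were shared. Its highest SOX17 peak covered the promoter (chromosome 6, 106086028 to 106086140, -236 bp from the TSS, percentile 96.9), where the SOX2 list had none. TFAP2C, encoding an AP-2 factor of early germ cells, had 6 SOX2 and 5 SOX17 peaks with 1 shared, and its highest peaks, at percentiles 96.5 and 98.4, lay 107179 bp and 74173 bp downstream of the TSS. The receptor tyrosine kinase gene KIT had a SOX17 peak in intron 1 (chromosome 4, 54668498 to 54668602, percentile 98.4) and SOX2 peaks at percentiles 3.8 and 51.0. The SOX2 gene had 5 SOX2 peaks and 1 SOX17 peak, which was shared, 16045 bp downstream of the TSS. The SOX17 gene had 1 peak in each list, at different positions and at percentiles of 21.0 for SOX2 and 60.5 for SOX17. GATA6, an endoderm regulator, had 3 SOX2 and 4 SOX17 peaks with none shared, among them a SOX17 promoter peak at percentile 48.2. FOXA2 and PAX6, regulators of endoderm and of neural and eye development, had no peak in either list. These assignments are to the nearest TSS, and a site missing from a list of merged peaks is not thereby shown to be unbound or uncalled in every replicate.

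**Figure D1:**
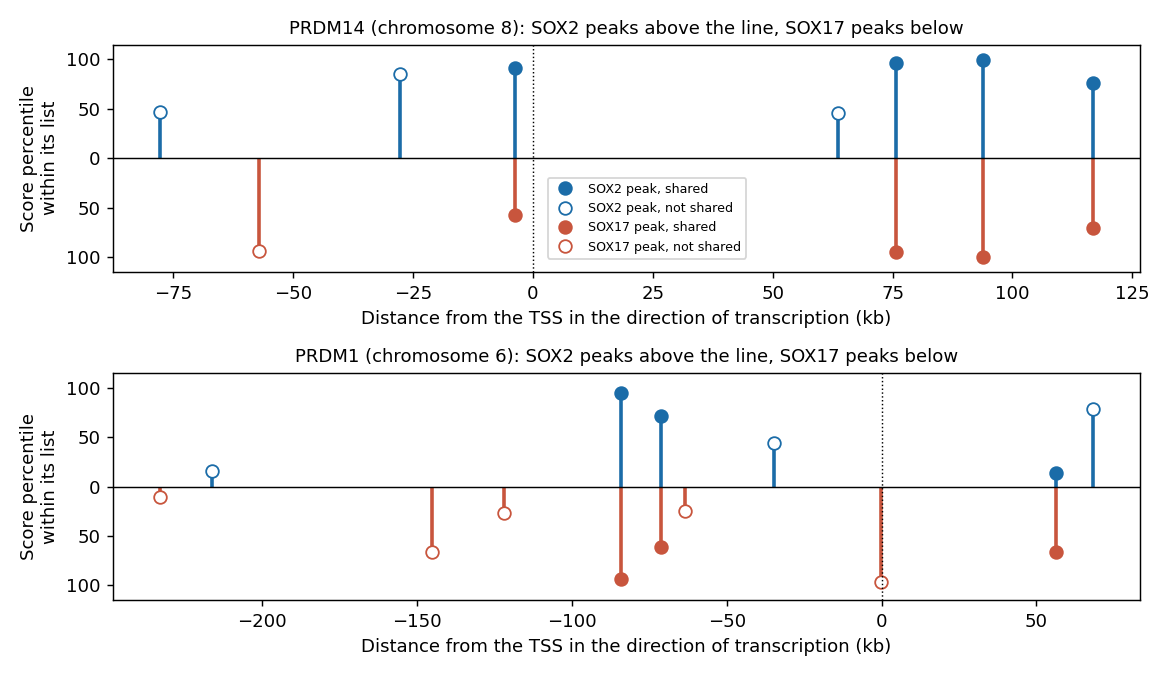
Peaks assigned to PRDM14 (upper panel) and PRDM1 (lower panel), by distance from the TSS in kb in the direction of transcription (x axis) and score percentile within the list (y axis); SOX2 peaks point up and SOX17 peaks down, and filled points are shared. PRDM14 has 4 shared peaks, and the PRDM1 promoter peak, at -236 bp from the TSS, is in the SOX17 list.

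The next comparison asked which groups of genes lay near the peaks, for 14 lists of genes set against random lists matched on locus size. Pluripotency genes stood furthest above chance in both, by observed over expected: 28 of 30 were nearest to a SOX2 peak, against 11.7 by chance (permutation test, adjusted p = 0.0014), and 23 of 30 to a SOX17 peak, against 12.0 (adjusted p = 0.0014). Their highest peaks belonged to NANOG, TERF1, PRDM14 and OTX2, whose promoter peak was shared at percentiles 99.8 for SOX2 and 92.5 for SOX17. Genes of FGF and MAPK signalling followed, with 25 of 28 near SOX2 peaks (11.9 by chance, permutation test, adjusted p = 0.0014) and 22 of 28 near SOX17 peaks (12.2, adjusted p = 0.00187). Among their highest peaks were those that belonged to the ERK phosphatase gene DUSP6, with a shared intronic peak, to the ERK pathway inhibitor gene SPRED2 and to FGF13.

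Nodal and BMP signalling genes were near SOX2 peaks in 22 of 34 cases (14.2 by chance, permutation test, adjusted p = 0.0184) and near SOX17 peaks in 25 (14.5, adjusted p = 0.0014), led by SMAD7, ID1, the BMP receptor gene BMPR1A and GDF3. Of 29 genes of WNT signalling 20 were near peaks of each factor (permutation test, adjusted p = 0.0238 for SOX2 and 0.0284 for SOX17), led by the secreted WNT antagonist gene SFRP2, WNT3, the receptor gene FZD7 and RSPO3. Genes of cell adhesion and migration, led by CD9, ITGA6, CXCR4 and CDH2, were near SOX2 peaks in 22 of 29 cases (permutation test, adjusted p = 0.00187) and near SOX17 peaks in 20 (adjusted p = 0.0238).

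Regulators of DNA methylation and chromatin passed the threshold for SOX2, with 15 of 27 genes (8.59 by chance, permutation test, adjusted p = 0.0238), and not for SOX17, with 11 genes (9.01, adjusted p = 0.565); their highest peaks belonged to HDAC2, JARID2, the DNA methyltransferase gene DNMT3B and KDM2B. Mesoderm and trophoblast genes, led by TEAD4, TBX3, WNT3 and MEOX1, likewise passed for SOX2 with 18 of 28 (permutation test, adjusted p = 0.0238) and not for SOX17 with 16 (adjusted p = 0.189). Primordial germ cell and seminoma genes passed for SOX17 with 18 of 30 (11.3 by chance, permutation test, adjusted p = 0.0238) and not for SOX2 with 16 (10.8, adjusted p = 0.0888). This group was led by the germ cell gene DND1, with a shared peak at percentiles 98.1 for SOX2 and 98.7 for SOX17, by DMRT1, with SOX17 at percentile 98.7 and SOX2 at 1.12, and by KIT and TFAP2C. The SOX family passed for SOX17 with 12 of 20 (permutation test, adjusted p = 0.0496) and not for SOX2 with 11 (adjusted p = 0.098), led by SOX5, SOX6, SOX14 and SOX3.

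The other lists passed for neither factor. Endoderm genes, among them CDX2, EOMES and COL4A1, were near SOX2 peaks in 12 and near SOX17 peaks in 13 of 30 cases (permutation test, adjusted p = 0.565 and 0.491). Neuroectoderm genes, led by NR2F2, HESX1, SOX3 and NES, were so in 14 and 12 of 35 cases (permutation test, adjusted p = 0.207 and 0.706). Genes of other cell types, haematopoietic (8 and 10 of 30, led by MPO, IL7R, GZMB and RUNX3; permutation test, adjusted p = 0.751 and 0.408) and muscle (10 and 5 of 30, led by CASQ2, MYL2, MYH2 and NEB; adjusted p = 0.401 and 0.469), did not pass. Housekeeping genes, led by TUBB, TFRC, EEF1A1 and YWHAZ, were near peaks in 6 and 9 of 28 cases (permutation test, adjusted p = 1.0 and 0.491).

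These p-values came from two-sided permutation tests with 10000 random lists, adjusted over 28 tests by the method of Benjamini and Hochberg. The smallest permutation p that 10000 lists can give is 0.0002, which over all peaks became 0.0014 after adjustment. Lists at that value cannot be ranked by p. Within 50000 bp of the TSS the SOX17 calls ended for the germ cell list (permutation test, adjusted p = 0.0772), WNT signalling (0.0611), the SOX family (0.335) and adhesion (0.0633), and among the higher-scoring peaks they ended for WNT signalling (0.266) and the SOX family (0.157). Within 50000 bp observed over expected was 1.64, 1.66, 1.52 and 1.64 for these lists in that order. Over all peaks it was 1.6, 1.5, 1.68 and 1.49. Among the higher-scoring peaks it was 1.41 for WNT signalling and 1.75 for the SOX family. Other calls began: among the higher-scoring peaks the SOX family passed for SOX2 (0.0149) and the DNA methylation and chromatin list for SOX17 (0.0352). With Fisher's exact test in place of matched lists the germ cell list (0.0279) and the SOX family (0.0466) passed for SOX2 and the mesoderm and trophoblast list for SOX17 (0.017). That test does not allow for locus size, and on simulated random peaks it gave 12 calls in 280 tests, where the matched test gave 0. Which factor the SOX family passed for therefore depended on the setting. It passed for SOX17 alone over all peaks and for SOX2 alone among the higher-scoring peaks. Within 50000 bp it passed for neither (permutation test, adjusted p = 0.0514 for SOX2). By Fisher's exact test it passed for both (adjusted p = 0.0271 for SOX17). Some genes, such as GDF3, TDGF1 and WNT3, belong to several lists, and NANOG, GDF3, CD9, SOX5 and TEAD4 lie on the short arm of chromosome 12, where scores ran higher.

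None of the 14 lists differed between genes near SOX2 peaks alone and genes near SOX17 peaks alone after adjustment (two-sided Fisher's exact tests). At an unadjusted p under 0.05 there was 1: of the pluripotency genes DNMT3B, GDF3, LIN28B, MYCN and POU5F1 were near SOX2 peaks alone and none near SOX17 peaks alone (Fisher's exact test, p = 0.0225, adjusted p = 0.315). This did not hold within 50000 bp of the TSS (Fisher's exact test, p = 0.107) or among the higher-scoring peaks (p = 0.0629), where other lists fell under 0.05 instead, DNA methylation and chromatin (p = 0.0306) and mesoderm and trophoblast (p = 0.034), none of them after adjustment. A list that passed for 1 factor is therefore not shown to differ between them.

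**Figure D2:**
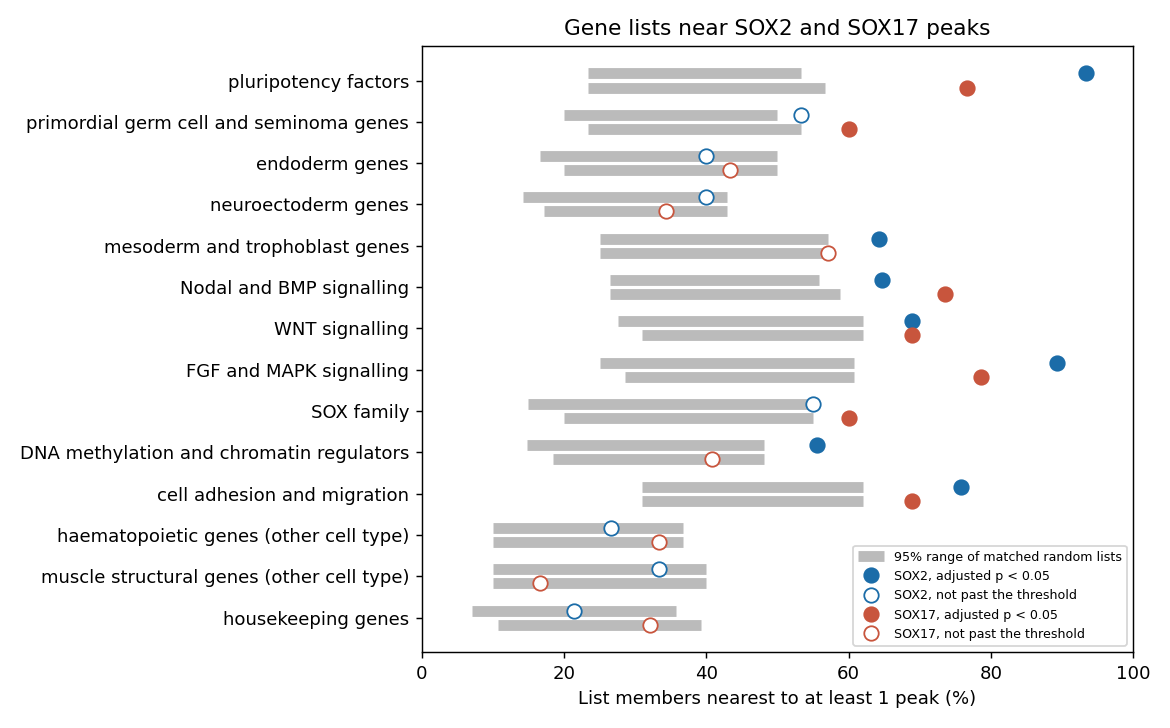
Share of each gene list that was nearest to at least 1 peak (x axis, percent), for SOX2 and SOX17; grey bars span 95% of the matched random lists, and filled points have an adjusted p under 0.05. The pluripotency list stands at 93.3% for SOX2 and 76.7% for SOX17.

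The sequence comparison asked whether SOX2 and SOX17 peaks held SOX and OCT sites at different spacings. A peak counted as holding a site when the site lay within 100 bp of the peak centre. The canonical composite site, with 1 base between the SOX and the OCT site, lay in 295 SOX2 peaks (1.66%, 95% Wilson interval 1.48 to 1.86%) and 64 SOX17 peaks (0.366%, 0.286 to 0.467%). The compressed site, with no base between them, showed the opposite: it lay in 14 SOX2 peaks (0.0787%, 0.0469 to 0.132%) and 485 SOX17 peaks (2.77%, 2.54 to 3.02%). The odds ratio of SOX17 over SOX2 was 0.218 for the canonical site (95% interval 0.166 to 0.285, adjusted p = 1.83e-35) and 36.2 for the compressed site (21.3 to 61.6, adjusted p = 3.39e-126; two-sided Fisher's exact tests adjusted over 11 spacings). The canonical site was more frequent in peaks than in flanking windows in both lists, with odds ratios of 60.0 for SOX2 and 10.7 for SOX17. For the compressed site these were 3.11 in SOX2 peaks (Fisher's exact test, adjusted p = 0.00892) and 90.7 in SOX17 peaks. The 9 control spacings, of 2 to 10 bases, mostly exceeded the flanking windows too, 7 of them in SOX2 peaks (odds ratios 2.63 to 21.5) and 9 in SOX17 peaks (2.46 to 11.6). The compressed site in SOX2 peaks and the canonical site in SOX17 peaks were therefore not enriched beyond the control range under the main settings. The SOX2 value for the compressed site rested on 14 peaks, and its call ended with windows of 50 bp (odds ratio 2.8) or no mismatch in the OCT part (odds ratio 2).

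Peaks with the canonical site and the highest SOX2 scores were assigned to the chromatin remodelling gene SMARCA2, FAM106A, MIR9-2 and RTL3, and 1, on chromosome 1 (52976345 to 52976454), had no gene in the list. At SMARCA2 (intron 1, site CATTGTTATGCAAAA at chromosome 9, 2018957 to 2018971) and at MIR9-2 (site CTTTGTAATGTAAAT at chromosome 5, 88664711 to 88664725) the same site lay within 100 bp of the centre of a shared SOX17 peak, and the other high SOX17 peaks with a canonical site were nearest to LINC02217, CRX and CDH4. Of the 4 shared PRDM14 peaks 2 held a canonical site, as did the highest SOX2 peak of the SOX2 gene, 4222 bp downstream of the TSS, and a SOX2 peak of GATA6. Compressed sites in the highest SOX17 peaks were nearest to CPNE8, PRMT8, FSAF1, FAR2 and PTPN5, all inside annotated endogenous retroviral repeats, and CTTTGTATGGTAAT was the sequence in all of these except FSAF1. PRMT8 and FAR2 lie on the short arm of chromosome 12, where scores ran higher. The second SOX17 peak of KIT, 28040 bp downstream of the TSS, and the highest SOX17 peaks of RSPO3 and COL4A1 also held a compressed site. In the SOX2 list the highest compressed sites were near CYP4A22, VGLL3, PCDHB8, HSF2 and CCDC50, at percentiles of 83.9 and below.

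Shared peaks cover nearly the same sequence in both lists and so held nearly the same sites, which places the difference between the lists in the unshared peaks by construction. Of 13369 unshared SOX2 peaks 244 held a canonical and 1 a compressed site, and of 13081 unshared SOX17 peaks 13 held a canonical and 473 a compressed site. In the 4426 shared peaks 51 canonical sites were found with either list's windows, and 13 compressed sites with the SOX2 and 12 with the SOX17 windows. Among SOX17 peaks, compressed sites were more frequent at and above the median score than below it (odds ratio 2.75, Fisher's exact test, p = 6.2e-25), and for canonical sites in SOX2 peaks this ratio was 1.11 (p = 0.41). Of the 485 SOX17 peaks with a compressed site 306 lay in repeats. The comparison by score was not repeated outside repeats or without the short arm of chromosome 12.

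None of the 9 control spacings differed between the lists, with odds ratios between 0.586 and 1.2 (Fisher's exact tests, lowest adjusted p = 0.431). With windows of 250 bp 1 of them did: 4 bases lay between the sites in 0.646% of SOX2 and 1.33% of SOX17 peaks (odds ratio 2.06, Fisher's exact test, adjusted p = 3.3e-10). The odds ratio of the compressed site was 67.0 with windows of 50 bp and 19.8 with windows of 250 bp. With 1 mismatch also allowed in the SOX part, an alternative chosen after seeing the data, the compressed site lay in 0.849% of SOX2 and 8.24% of SOX17 peaks and the canonical site in 9.68% and 2.49% (odds ratios 10.5 and 0.238). Under that looser rule 8 of the 9 control spacings differed between the lists as well, with odds ratios between 0.6 and 1.17. Over flanking windows the canonical site in SOX17 peaks then stood at an odds ratio of 5.0 (95% interval 4.19 to 5.96), against at most 4.24 for the control spacings. With windows of 100 bp and no mismatch in the SOX part, the control spacings of 4 and 5 bases stood highest over the flanking windows, in 62 and 75 SOX2 peaks and 66 and 58 SOX17 peaks, and this order changed under other settings.

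**Figure D3:**
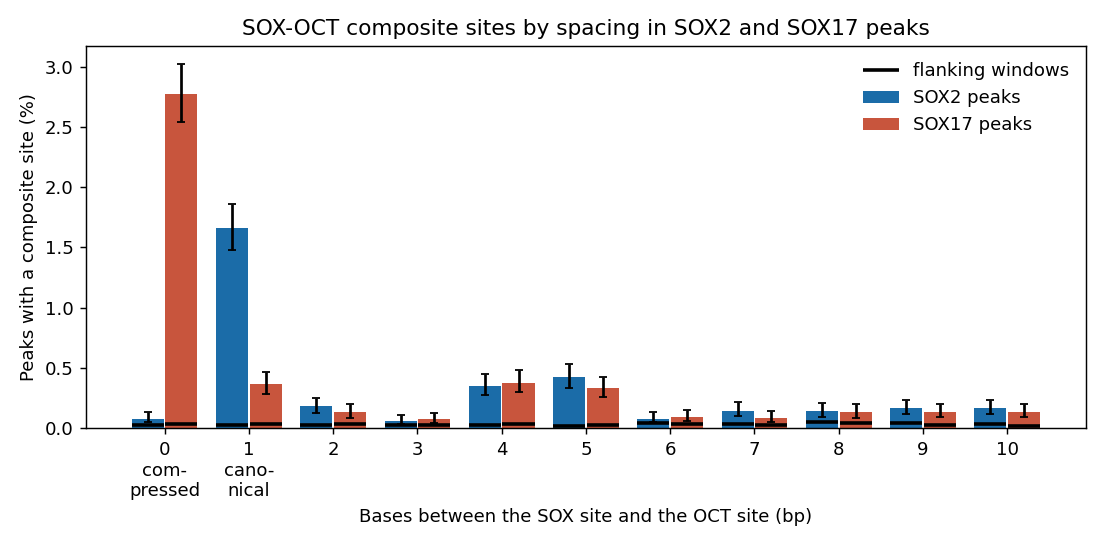
Share of peaks with a SOX-OCT composite site (y axis, percent) by the number of bases between the SOX and the OCT site (x axis); bars are SOX2 and SOX17 peaks, error bars 95% Wilson intervals and black lines the flanking windows. The canonical site stands at 1.66% of SOX2 and 0.366% of SOX17 peaks, the compressed site at 0.0787% and 2.77%.

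Single sites were also compared. A SOX site lay in 60.5% of SOX2 and 67.1% of SOX17 peaks (odds ratio SOX17 over SOX2 1.34, Fisher's exact test, adjusted p = 1.1e-38), against 24.5% and 24.8% of flanking windows. An OCT site lay in 15.1% of SOX2 and 11.5% of SOX17 peaks (odds ratio 0.728, Fisher's exact test, adjusted p = 7e-24), against 2.47% and 2.43% of flanking windows. The AP-2 site, bound by TFAP2C and its relatives, lay in 6.42% of SOX2 and 11.9% of SOX17 peaks (odds ratio 1.97, Fisher's exact test, adjusted p = 3.1e-72), against 3.49% and 3.72% of flanking windows. A reversed sequence of the same composition also differed between the lists, with an odds ratio of 1.43 (two-sided Fisher's exact tests).

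Most peaks of both factors lay away from promoters. Intergenic peaks were 51.0% of the SOX2 and 49.3% of the SOX17 list (Fisher's exact test, adjusted p = 0.005), and intronic peaks numbered 7733 and 7709 (adjusted p = 0.45). Promoter peaks were rarer for SOX2, with 456 (2.56%, 95% Wilson interval 2.34 to 2.81%), than for SOX17, with 581 (3.32%, 3.06 to 3.59%; odds ratio 1.31, adjusted p = 0.00022; two-sided Fisher's exact test over 8 classes). Exons held 0.427% of SOX2 and 0.64% of SOX17 peaks (Fisher's exact test, adjusted p = 0.018). Peaks in 3' UTRs, in 5' UTRs, at transcription termination sites and in non-coding transcripts made up 0.747, 0.174, 1.19 and 0.444% of the SOX2 list and 0.817, 0.217, 1.13 and 0.565% of the SOX17 list, with adjusted p-values of 0.54, 0.53, 0.62 and 0.23. The intergenic and exon differences did not pass among the higher-scoring peaks (Fisher's exact test, adjusted p = 0.17 in each). Their odds ratios of SOX17 over SOX2 were 0.943 and 1.52 there, against 0.934 and 1.5 over all peaks.

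Annotated repeats held 41.4% of SOX2 and 43.1% of SOX17 peaks (odds ratio 1.07, Fisher's exact test, adjusted p = 0.0015; 1.04 and adjusted p = 0.21 among the higher-scoring peaks). LTR elements, the remains of endogenous retroviruses, held more of the SOX2 list, 25.5% against 22.6% (odds ratio 0.853, Fisher's exact test, adjusted p = 3.9e-10). LINE elements held more of the SOX17 list, 11.8% against 8.9% (odds ratio 1.37, Fisher's exact test, adjusted p = 1.2e-18), as did SINE elements, 3.22% against 2.56% (1.27, adjusted p = 0.00033), and the retroposon class, 1.86% against 0.95% (1.98, adjusted p = 8.3e-13). DNA transposons held 3.04% and 2.74% (adjusted p = 0.092; two-sided Fisher's exact tests over 6 classes). How reads that map to several places were treated is not given in the sources used here.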

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

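Results in this part are those whose enrichment in peaks over flanking windows differed between the SOX17 experiment in TCam-2 and the SOX2 experiment in 2102EP, by a test of the ratio of the 2 odds ratios; the test of base composition for the compressed spacing was chosen after the result was seen. The ratio, SOX17 over SOX2, was 29.1 for the compressed spacing (95% interval 10.4 to 81.5) and 0.178 for the canonical spacing (0.0739 to 0.431). It was 1.32 for the SOX site (1.25 to 1.39), 0.74 for the OCT site (0.66 to 0.829) and 1.84 for the AP-2 site (1.65 to 2.06). These 5 passed an adjusted threshold of 0.05 and none of the 9 control spacings did, with windows of 100 bp. The intervals rest on a normal approximation, which is rough for the compressed spacing, found in 14 SOX2 peaks.

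The compressed spacing could reflect copies of repeats that carry the site, since 306 of the 485 SOX17 peaks with it (63.1%) lay in repeats and 188 held the same sequence, CTTTGTATGGTAAT. Outside annotated repeats the odds ratio of SOX17 over SOX2 was still 23.8 (11.7 to 48.4), which argues against repeats as the whole cause. The sequence held by 188 peaks has 1 mismatch in its OCT site. With no mismatch allowed there, 40 SOX17 and 1 SOX2 peaks held a compressed site (odds ratio 40.7, 5.6 to 296). These peaks were not compared outside repeats, and at least 1 SOX17 peak among them, nearest to FSAF1, lay in a repeat. Repeats also held 119 of the 295 SOX2 peaks with a canonical site (40.3%). Outside repeats the odds ratio of the canonical site was 0.235 (0.166 to 0.331). Base composition would move all spacings, and the highest odds ratio among the control spacings was 1.2, or 2.06 with windows of 250 bp, where that of the compressed spacing was 19.8 (13.3 to 29.3), which argues against composition as the whole cause. A preference of SOX17 for compressed SOX-OCT sites is a candidate explanation that these tests leave open, as is a difference between the lines in open chromatin or partner factors. Antibody and line changed together, and neither was tested.

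The AP-2 sites could follow from base composition, as SOX17 windows had 45.6% GC and SOX2 windows 44.1%. The reversed sequence GGCNNNGCC had an odds ratio of 1.43 (1.3 to 1.56), below that of the AP-2 site, 1.97 (1.83 to 2.13), so by this control alone composition may account for part of the difference but not for all of it. Outside promoters the AP-2 odds ratio was 1.97 (1.82 to 2.13), which argues against the larger number of SOX17 promoter peaks as its source. Promoter peaks were few, 456 for SOX2 and 581 for SOX17, against 1142 and 2087 peaks with an AP-2 site. Leaving them out could therefore change the ratio only a little. Single sites were not compared outside repeats, which held 41.4% of SOX2 and 43.1% of SOX17 peaks, so copies of repeats were not tested as a source. Binding near TFAP2C in TCam-2 remains a hypothesis that was not tested.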

How the results depend on the processing

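The alternatives that used peaks outside repeats or a mismatch in the SOX site were chosen after seeing the data. Of 159 alternative values 139 kept their side of the threshold, or stayed within 1.5 times for counts, 9 lost and 5 gained a call, 6 counts moved and 0 reversed. A reversal was counted only where the direction changed and the main or the alternative value passed the threshold. Values that passed in neither were counted as kept even when their direction changed. For haematopoietic genes near SOX2 peaks, observed over expected was 1.17 over all peaks and 0.493 among the higher-scoring peaks. Of the 159 values, 84 concerned single gene lists, with 73 kept, 6 lost and 5 gained. The higher-scoring peaks numbered 8907 for SOX2 and 8832 for SOX17 by construction, with 1943 shared peaks and 3164 shared genes, and within 50000 bp of the TSS 3985 genes were shared and 3 lists were called for SOX17; fewer peaks entered each of these. Among the higher-scoring peaks the odds ratio for any repeat was 1.04 and no longer passed. The compressed spacing in SOX2 peaks over flanking windows no longer passed with windows of 50 bp (odds ratio 2.8) or with no mismatch in the OCT site (odds ratio 2), where fewer sites entered. The overlap, the scores of shared peaks, the promoter share and the differences of both spacings between the lists kept their calls under every alternative run for them. The size of the latter moved, from 10.5 to 67 for the compressed spacing, with 67 in windows of 50 bp and 19.8 in windows of 250 bp, and from 0.199 to 0.338 for the canonical spacing. In windows of 250 bp 1 of the 9 control spacings, of 4 bases, also differed between the lists (odds ratio 2.06), and the cause was not tested. No paired analysis was possible because the lists hold merged peaks with no column per library. For the same reason 4 alternatives set in advance for the ChIP against input test were not run: the replicate block, leaving out each replicate, the other pseudocount or count tool, and the filter on low values. With a mismatch also allowed in the SOX site the odds ratios between the lists were 10.5 for the compressed and 0.238 for the canonical spacing, but 8 of 9 control spacings then differed too, and the cause was not tested. Depth is unknown, so how it limits the number of peaks cannot be stated.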

Other observations

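The tests of repeat families below, and the use of the lower quartile against a few strong peaks on chromosome 12, were chosen after the data were seen. Some repeat families held more SOX2 and others more SOX17 peaks, and for others no difference passed the threshold. Of 145 repeat families with at least 20 peaks in both lists together, 31 held more of the SOX2 list and 36 more of the SOX17 list at an adjusted p under 0.05 (two-sided Fisher's exact tests). LTR7, the LTR of the HERV-H family, held 413 SOX2 and 111 SOX17 peaks (odds ratio SOX17 over SOX2 0.269, Fisher's exact test, adjusted p = 2.2e-39), while HERVH-int of the same family held 11 and 40 (3.7) and LTR7B 32 and 60 (1.91). MER4E1 held 151 and 22, LTR49 92 and 8 and LTR9B 85 and 4. LTR8A held 73 SOX2 and 10 SOX17 peaks, and 27 of the SOX2 peaks had a canonical site. On the SOX17 side THE1B-int held 294 against 108 SOX2 peaks, MER4A1 210 against 49 and MER41B 82 against 18. HERV17-int held 89 SOX17 and 10 SOX2 peaks (odds ratio 9.09, Fisher's exact test, adjusted p = 3.4e-16), and 69 of the 89 had a compressed site. LTR5_Hs with 206 SOX2 and 234 SOX17 peaks, MSTA-int with 197 and 219 and MSTB-int with 107 and 86 did not pass (Fisher's exact tests, adjusted p = 0.22, 0.33 and 0.26). Copies within a family are alike in sequence, and how reads with several map positions were treated is not given in the sources used here.

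SOX2 peaks on the short arm of chromosome 12, taken as the first 35 Mb, had a median score of 47.4 (95% bootstrap interval 43.5 to 55.6) against 23.8 elsewhere, and SOX17 peaks 40.7 (37.7 to 46.0) against 26.3. Of the 100 highest SOX2 peaks 12 lay there, although the arm held 1.66% of all SOX2 peaks. A few strong peaks would leave the weaker peaks of the arm at the usual level, but the lower quartile of SOX2 scores there was 28.6 (26.9 to 31.8) against at most 18.2 elsewhere, which argues against them. Extra copies of the whole arm, which are common in germ cell tumours, may account for the pattern, since they would raise weak peaks as well as strong ones. Copy number was not measured, since input values were not analysed here.

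Composite sites with 4 or 5 bases between the SOX and the OCT site were more frequent than in flanking windows outside repeats as well. The odds ratio was 9.31 (4.85 to 17.9) in SOX2 and 14.6 (6.64 to 32.3) in SOX17 peaks. This was not particular to these spacings, since 8 of the 9 control spacings passed the threshold outside repeats in each list. Among the control spacings there, that of 2 bases stood highest in SOX2 peaks, with an odds ratio of 13.4. In SOX17 peaks that of 4 bases stood highest, at 26.1.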
